A study of Oryza sativa Japonica Group with 8 samples.

How the data were processed

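The study measured transcript levels in 8 libraries of japonica rice (Oryza sativa) by strand-specific RNA sequencing of polyadenylated RNA. The 8 groups, with 1 library each, were mature seeds, milk grains, flower buds, flowers, and both flag leaves and roots from plants that had or had not yet flowered. Plants grew in a greenhouse, and the leaf and root samples of each period pooled several stages, per the labels' protocols. Libraries were made with an Illumina stranded mRNA kit and sequenced on an Illumina HiSeq instrument, per the labels' protocols. TopHat, Cufflinks and Cuffdiff are named in the submitters' processing notes, and their versions and settings are not given in the sources used here.

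The deposited table gives values for 41805 loci, per its name as FPKM, a measure of fragments scaled by length and by mapped reads. How the length of short loci entered that scaling is not given in the sources used here. Positions refer to Release 7 of the MSU rice genome annotation, per the file headers. Of these loci, 20712 lie on the plus strand and 21093 on the minus strand. The table pairs its locus identifiers with no gene names. The reference table of 39387 genes is on another assembly, ASM3414082v1, and 0 of the file's identifiers were found in it. The 16 gene lists fixed in advance held 187 entries, covering seed storage, photosynthesis, floral organs, root transport and other functions. None of their identifiers was found in the file, so the list results and the named genes planned with them were not computed, and loci are given by identifier and position only. Whether a locus is exonic, intronic or untranslated is likewise not given.

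Read totals are not given in the sources used here. At loci of 101 bp, however, 212 of 212 checked values lay within 0.03 of a whole multiple of a per-library, per-strand step, among values under 60 steps. These steps give depth relative to mature seeds, the shallowest library. The step on the minus strand was 7.48% to 10.9% larger than that on the plus strand in the same library, so the 2 strands carry different scales. Loci under 300 bp make up 8.81% of all loci and 27.4% to 49.7% of the FPKM sum of a library.

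Ratios were taken as log2 of (FPKM + 1) in the later library over (FPKM + 1) in the earlier library, which understates the change of loci with low values. Loci with at least 1 FPKM in either library were compared, and loci at least 4-fold apart were counted. A locus was called enriched in an organ when the lower value among the organ's libraries was at least 1 FPKM and at least 4-fold above the highest value in any other organ, again on the FPKM + 1 scale. With 1 library per group there is no replicate check on any difference, so no test was run and no p-value is given. These rules, the gene lists and the settings named as fixed in advance were set before the data were examined.

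Other choices were made after the data were seen. Organ sets replaced the gene lists: for each comparison, loci of at least 300 bp and 10 FPKM that stood at least 4-fold above other organs, chosen without the compared organ and without the library labelled roots sampled after flowering. Limits of 4-fold and 16-fold were both examined before 4-fold was kept. The median log2 ratio of a set is given with its percentile among 10000 random lists of the same size, matched over 20 bins of mean expression, as a description of these libraries. Neighbouring loci were counted in windows of 200 kb, with loci of at least 300 bp and, for the stage comparisons, above 0 in both libraries. Windows with at least 5 such loci were compared with 1000 shuffles of the calls over loci. The planned rule for printed genes needed names. In its place, the 2 loci with the largest and the 2 with the smallest ratio were printed, among loci of at least 500 bp that were above 0 in both libraries and at 10 FPKM or more in the higher one. This rule was set after loci of 101 bp and exact zeros had been seen to lead the ranking.

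Other settings fixed in advance were a pseudocount of 0.1, a filter at 5 FPKM or none, a 2-fold limit, detection limits of 0.1 and 5 FPKM, and rescaling of each library to a sum of 1000000 or by its median ratio over 25795 loci above 0 in all libraries. Rescaling to a sum of 1000000, called equal sums below, divided libraries by 2.13 to 5.31 and kept the pseudocount at 1. The pseudocount therefore weighed more, and ratios at low values shrank even where sums were already alike. The counts of changed loci were tested on simulated data in which 200 loci were changed 8-fold with noise of 20%, among loci of at least 5 FPKM in the earlier library. Recovery at lower values, which the reported counts include, was not tested. An 8-fold rise with noise of 20% seldom falls under 4-fold, so recovery of raised loci was close to fixed in advance. Unequal depth, exact zeros and the steps at loci of 101 bp were not simulated, so false calls from these were not tested. All raised loci were recovered, and 87% of lowered loci for flowers against flower buds, 95% for leaves, 90% for roots and 100% for seeds, over 21838, 19921, 20367 and 21163 loci. The percentile calculation, without matching on expression, was run on 200 simulated lists of 100 loci for flowers against flower buds, drawn from 29590 loci. With no effect put in, 4.5% fell outside the central range from 2.5 to 97.5. Lists and reference lists came from the same loci, so this checks the calculation only. The matching and the sizes of the reported sets were not tested. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.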

Results

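Transcript levels were profiled in rice organs across flowering and grain filling. Libraries came from flower buds, flowers collected on the flowering day, flag leaves (the uppermost leaf of a flowering shoot) and roots before and after flowering, milk grains (immature grains with fluid contents) and mature seeds. Each of the 8 groups had 1 library, so the differences given here have no replicate check. Between 25914 loci in mature seeds and 30200 loci in flower buds reached 1 FPKM. The corresponding counts were 29669 in flowers, 27275 in leaves before flowering, 27235 in leaves after flowering, 28410 in roots before flowering, 28012 in the library labelled roots sampled after flowering and 29246 in milk grains. Read totals were unknown, but depth relative to mature seeds was 2.56 in flower buds, 2.41 in flowers, 2.04 and 2.85 in leaves before and after flowering, 1.65 in roots before flowering and 1.94 in milk grains. The library labelled roots sampled after flowering was 7.79 times as deep as mature seeds.

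The 10 highest loci held 13.7% of the FPKM sum in flower buds and 29.3% in mature seeds. The locus P_XLOC_017791 on chromosome 3 (4117574 to 4117871, plus strand, 298 bp) had the highest value in flower buds, flowers, leaves after flowering, the library labelled roots sampled after flowering, milk grains and mature seeds, at 119364 FPKM in flower buds and 496484 FPKM in mature seeds.

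Leaves before and after flowering correlated at 0.91 (Spearman, across loci, which are not independent replicates), and flower buds and flowers at 0.90. The library labelled roots sampled after flowering correlated at 0.96 with leaves after flowering and at 0.91 with leaves before flowering, but at 0.63 with roots before flowering. It differed at least 4-fold from leaves after flowering at 653 loci and from roots before flowering at 10081 loci, against 2496 loci between the leaf libraries. Roots before flowering correlated at 0.65 or less with every other library. Milk grains and mature seeds correlated at 0.72.

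**Figure D1:**
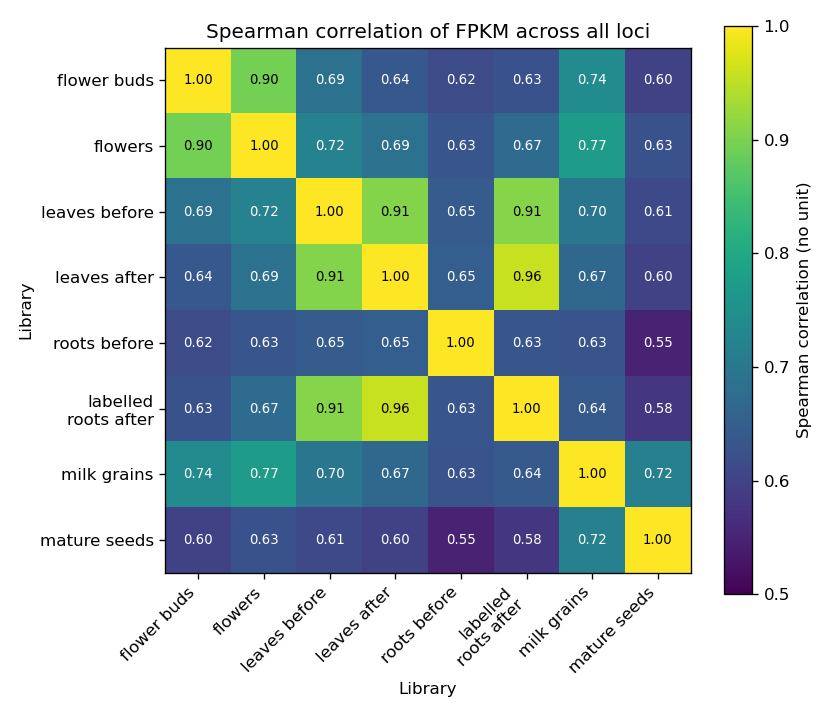
Spearman correlation of FPKM across all loci between each pair of the 8 libraries, with the value in each cell and no unit. The library labelled roots sampled after flowering stands at 0.96 with leaves after flowering and at 0.63 with roots before flowering.

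Organ identity was described by loci enriched in an organ over all others. Across the 8 libraries, 745 loci were enriched in inflorescences (flower buds and flowers) and 525 in seeds, but 5 in flag leaves and 8 in roots. With equal sums and the pseudocount still at 1, 286 loci were enriched in seeds. With a pseudocount of 0.1 the counts were 1163 for inflorescences, 807 for seeds and 20 for roots. Among loci of at least 300 bp, 3 were enriched in flag leaves and 1 in roots. Without the library labelled roots sampled after flowering, 752 were enriched in inflorescences, 492 in flag leaves, 532 in seeds and 2336 in roots, the last resting on 1 root library. When that library was instead counted as a leaf library, 465 loci were enriched in the 3 libraries. The 492 leaf loci had a median of 46.7 FPKM in leaves before flowering, 85.9 in leaves after flowering and 90.1 in the library labelled roots sampled after flowering, against 0.391 in roots before flowering. The 2336 root loci had a median of 51.9 FPKM in roots before flowering and 0.366 in the library labelled roots sampled after flowering.

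**Figure D2:**
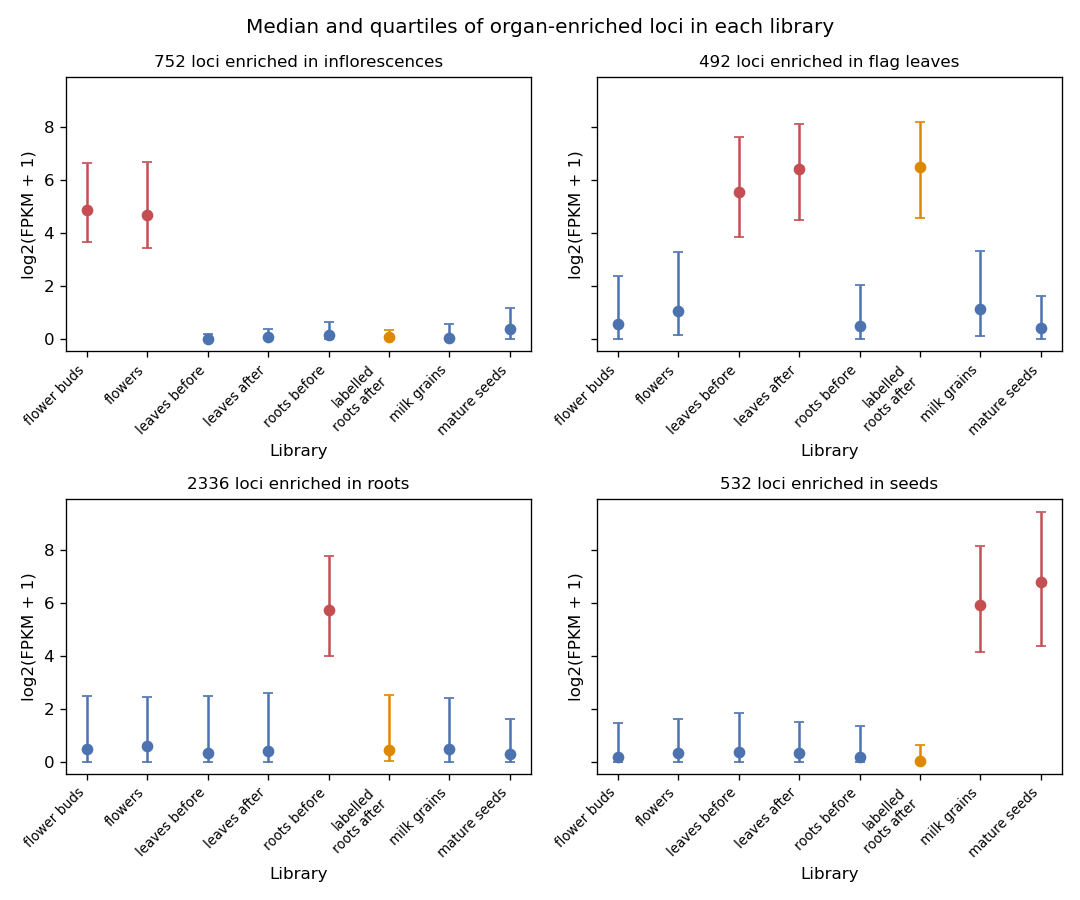
Median and quartiles of log2(FPKM + 1) in each library for loci enriched in inflorescences, flag leaves, roots or seeds, chosen without the library labelled roots sampled after flowering (orange); the organ's own libraries are red and the others blue. Leaf loci stand at a median log2 value of 6.51 in the orange library, beside 5.58 and 6.44 in the leaf libraries.

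Enriched loci lay close together in some regions (MSU Release 7). Counts are out of all loci in a window of 200 kb, and positions give the span of the enriched or changed loci only. In 1 window on chromosome 9, 8 of 24 loci were enriched in inflorescences, spanning 14294062 to 14344912. In 1 window on chromosome 1, 8 of 44 loci were enriched in flag leaves, spanning 851764 to 980699. On chromosome 5, 7 of 16 loci in 1 window and 6 of 14 in the next were enriched in seeds, spanning 15266310 to 15399097 and 15401029 to 15530862. Windows of 200 kb with at least 5 enriched loci numbered 4 for inflorescences, 4 for flag leaves, 66 for roots and 4 for seeds, where shuffling gave at most 2, 1, 36 and 1.

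The first stage comparison asked how transcript levels differ between flower buds and flowers. Of 566 loci otherwise enriched in flag leaves, 56 were at least 4-fold higher in flowers, 11 were lower and 499 were neither, with a median log2 ratio of 0.32 (percentile 100 of matched random lists). Root loci had a median of -0.28 (percentile 0), with 43 of 1284 higher and 93 lower. Seed loci had a median of -0.02 (percentile 88.8). Of these 401 loci, 31 (7.73%) were higher and 13 (3.24%) lower, against 3.08% and 3.61% of compared loci of any length. The direction of these medians was the same under each rescaling. With a 16-fold set limit the leaf-locus median was 1.34, over 72 loci.

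Among 32324 loci compared, 995 were at least 4-fold higher in flowers and 1166 lower, and 722 and 837 among loci of at least 300 bp. M_XLOC_039425 on chromosome 9 (5643294 to 5645523, minus strand) stood at 1336 FPKM in flowers and 1.62 in flower buds. P_XLOC_022337 on chromosome 4 (8584304 to 8585030, plus strand) stood at 2636 and 4.10 FPKM, but also at 6690 FPKM in the library labelled roots sampled after flowering and 11402 in mature seeds. M_XLOC_003021 on chromosome 1 (23311171 to 23312581, minus strand) was at 896 FPKM in flower buds and 0.486 in flowers. M_XLOC_025261 on chromosome 4 (30851812 to 30856049, minus strand) was at 8204 and 10.03 FPKM, and at 2179.6 FPKM or more in every other library. In 1 window on chromosome 9, 9 of 23 loci were lower in flowers, spanning 14294062 to 14344912, the same span as the inflorescence-enriched loci. Windows with at least 5 higher or lower loci numbered 2 and 2, within the shuffled maxima of 2 and 3 but above the shuffled means of 0.138 and 0.281. With a pseudocount of 0.1 the counts were 1923 and 2295.

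The second comparison set flag leaves after flowering against flag leaves before flowering. Of 1609 root loci, 242 were at least 4-fold higher after flowering, 88 were lower and 1279 were neither, with a median log2 ratio of 0.43 (percentile 100). That median was 0.24 with equal sums, where the pseudocount of 1 also weighed more on divided values, and 0.71 at a 16-fold set limit. Seed loci had a median of -0.34 (percentile 0), with 10 of 227 higher and 9 lower. A separate set of 65 abundant seed loci stood at medians of 0.0883% of their seed level in leaves before flowering and 0.0667% after, low values whose source is weighed among the additional observations. Inflorescence loci had a median of -0.54 (percentile 0), with 7 of 150 higher and 15 lower, but with a 16-fold set limit the median was 0.61, over 35 loci. The medians of these seed and inflorescence loci stayed negative under each rescaling at the 4-fold limit, and that of inflorescence loci was -0.33 with equal sums.

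Of 29611 loci, 1447 were at least 4-fold higher after flowering and 1049 lower, and 1055 and 769 among loci of at least 300 bp. P_XLOC_020343 on chromosome 3 (31281909 to 31285289, plus strand) was at 6795 FPKM after and 15.1 before flowering, and at 4952 in the library labelled roots sampled after flowering. M_XLOC_033028 on chromosome 7 (1668664 to 1669791, minus strand) was at 339 and 0.137 FPKM. P_XLOC_015587 on chromosome 2 (24566319 to 24568375, plus strand) was at 39.2 FPKM after and 12788 before flowering. M_XLOC_003899 on chromosome 1 (32381051 to 32385694, minus strand) was at 69.9 and 33104 FPKM. Its values in other libraries were 26833 in flowers, 26829 in roots before flowering and 13.9 in milk grains. Higher loci lay together in 1 window on chromosome 1, with 9 of 40 loci, spanning 839386 to 980699. In 1 window on chromosome 9 they made up 8 of 21 loci, spanning 13919744 to 13974649. Windows with at least 5 higher loci numbered 16, where shuffling gave at most 5. Those with 5 lower loci numbered 2, within the shuffled maximum of 3 but above the shuffled mean of 0.271. With a pseudocount of 0.1 the counts were 2500 higher and 2090 lower. Rescaling to equal sums, with the pseudocount and filter kept at 1 on the divided values, gave 774 higher and 621 lower among 23641 loci. The sums of this pair were already close, and median-ratio rescaling gave 1337 higher and 1130 lower.

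The third comparison set the library labelled roots sampled after flowering against roots before flowering, and any direction here rests on that label. Of 541 leaf loci, 355 were at least 4-fold higher in the library labelled after flowering, 24 were lower and 162 were neither, with a median log2 ratio of 3.43 (percentile 100) and median values of 117 against 9.35 FPKM. Inflorescence loci had a median of -1.44 (percentile 0), with 1 of 193 higher and 73 lower. Seed loci had a median of -1.37 (percentile 0), with 8 of 207 higher and 66 lower. These directions were the same under each rescaling and at a 16-fold set limit, but the sizes moved. With equal sums the medians were -0.63 for inflorescence loci and -0.65 for seed loci. The sums of this pair were already close, and the pseudocount of 1 weighed more on the divided values. The median of all loci of at least 300 bp was 0.057 as deposited and 0.059 after that rescaling. At the 16-fold limit the medians were -0.81 for inflorescence loci and 5.48 for leaf loci.

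Of 33668 loci, 4537 were at least 4-fold higher and 5544 lower, and 3392 and 5143 among loci of at least 300 bp. P_XLOC_018847 on chromosome 3 (14567424 to 14573315, plus strand) was at 21747 FPKM in the library labelled after flowering and 0.904 in roots before flowering. It was at 42913 and 45050 FPKM in leaves before and after flowering. P_XLOC_022337, described above, was at 6690 and 1.17 FPKM, and at 5.61 and 5.52 FPKM in leaves before and after flowering. P_XLOC_003864 on chromosome 1 (38818686 to 38822386, plus strand) was at 2.19 and 15009 FPKM, and at 4587 and 237 FPKM in leaves before and after flowering. M_XLOC_016066 on chromosome 2 (22509898 to 22510548, minus strand) was at 4.83 and 26996 FPKM. In 1 window on chromosome 1, 20 of 32 loci were higher, spanning 804084 to 1007068, a region that overlaps the leaf-enriched region. Windows with at least 5 lower loci numbered 303, above the shuffled maximum of 261, and those with 5 higher loci numbered 82, within the maximum of 92. With a pseudocount of 0.1, 6858 were higher. Rescaling to equal sums, with the pseudocount and filter kept at 1 on the divided values, gave 2807 higher and 3364 lower among 26080 loci. Median-ratio rescaling moved the median of all loci by -0.22, from 0.14 to -0.08.

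The fourth comparison set mature seeds against milk grains. Of 338 leaf loci, 22 were at least 4-fold higher in mature seeds, 89 were lower and 227 were neither, with a median log2 ratio of -0.98 (percentile 0). Inflorescence loci had a median of -1.37 (percentile 0), with 80 of 703 higher and 284 lower, but with a 16-fold set limit the median was 1.01, over 262 loci. Root loci had a median of -0.30 (percentile 62.9), with 190 of 1319 higher and 240 lower, and it was -0.46 with equal sums and -0.058 at the 16-fold limit. Rescaling to equal sums, with the pseudocount and filter kept at 1, moved the median of all loci by -0.48. Relative to the median of all loci of at least 300 bp, the root-locus median was -0.13 as deposited and 0.03 after that rescaling, a change of sign, while leaf loci stood at -0.80 and -0.34 and inflorescence loci at -1.19 and -0.63.

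Of 32377 loci, 3731 were at least 4-fold higher in mature seeds and 5628 lower, and 3002 and 4894 among loci of at least 300 bp. Higher loci made up 39.9% of changed loci as deposited. After rescaling to equal sums, with the pseudocount and filter kept at 1, they made up 23.6%, with 1273 higher and 4127 lower. With a pseudocount of 0.1, 8564 were lower. P_XLOC_015399 on chromosome 2 (22622379 to 22623188, plus strand) was at 59197 FPKM in mature seeds and 44.1 in milk grains. P_XLOC_035539 on chromosome 8 (1246065 to 1247034, plus strand) was at 3761 and 1.96 FPKM, but at 944 FPKM or more in every other library. P_XLOC_037367 on chromosome 8 (21337593 to 21354581, plus strand) was at 21.6 FPKM in mature seeds and 16668 in milk grains, and at 6120.01 FPKM or more in every other library. M_XLOC_019509 on chromosome 3 (12871282 to 12873556, minus strand) was at 1.62 and 1464 FPKM. Higher loci lay together in 1 window on chromosome 5, with 10 of 39 loci, spanning 26801890 to 26949834. Windows with at least 5 higher loci numbered 70, where shuffling gave at most 67, and those with 5 lower loci numbered 200, within the maximum of 220.

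**Figure D3:**
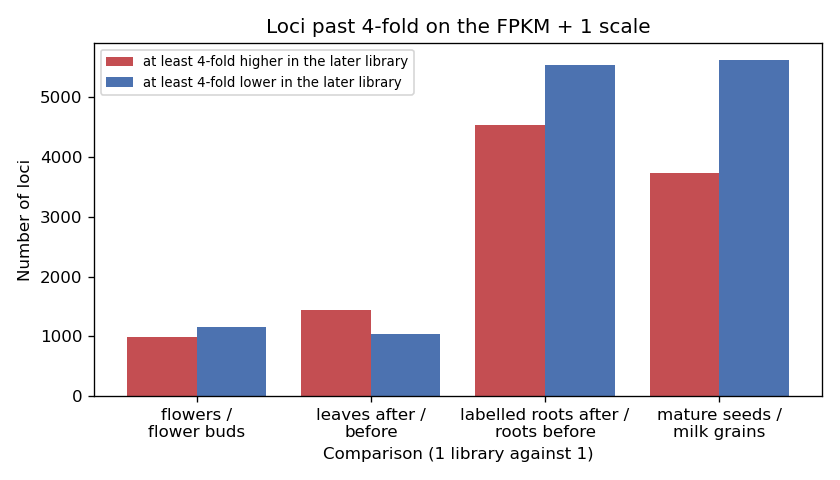
Number of loci at least 4-fold higher (red) or lower (blue) on the FPKM + 1 scale in the later library of each of the 4 comparisons, with 1 library on each side. The comparison with the library labelled roots sampled after flowering holds 4537 and 5544 loci, and that of seeds 3731 and 5628.

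The change after flowering in leaves was then set beside that in the libraries labelled roots, which share no library. Across 34928 loci the log2 ratios correlated at 0.13 (Pearson) and 0.09 (Spearman). In both pairs of libraries 591 loci were at least 4-fold higher, where independent lists would share 188, and 300 were at least 4-fold lower, where independent lists would share 167. These independent numbers include loci too low in 1 pair to be called there, so they are a rough guide. The later library of the root pair correlated at 0.96 with the later leaf library.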

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

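All tests in this part were chosen after the results they bear on had been seen.

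Some loci changed in opposite directions after flowering in leaves and in the libraries labelled roots. At least 4-fold lower in leaves and 4-fold higher in the libraries labelled roots were 231 loci, where independent lists would share 136. At least 4-fold higher in leaves and 4-fold lower in the libraries labelled roots were 184 loci, where independent lists would share 230. Each of these 4 libraries is the only library of its label, and the difference was not tested. It is a difference between organs only if the label of the library labelled roots sampled after flowering holds.

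The library labelled roots sampled after flowering resembled leaves, but a swap with another library of the series is argued against, because roots before flowering correlated at most at 0.65 (Spearman) with any other library. Leaf material mixed into root RNA is argued against too: 470 loci specific to roots before flowering had a median of 0.19% of their level there, and the highest stood at 7.49%. A leaf library under the root label may account for the pattern, since 653 loci differed 4-fold from leaves after flowering, fewer than the 2496 between the leaf libraries. However, P_XLOC_022337 stood at 6690 FPKM in the doubted library and at 5.61 and 5.52 in leaves before and after flowering, and P_XLOC_003864 at 2.19 against 4587 and 237. The other printed loci of that comparison, P_XLOC_018847 and M_XLOC_016066, lay nearer to the leaf libraries than to roots before flowering. Whether the doubted library shares material with a leaf library stays open. Chi-square per degree of freedom over reads at the shortest loci was 2.82 against leaves after flowering, 1.44 against leaves before flowering and 1.73 between the leaf libraries. These pairs held 254 and 793 reads over 38 loci, 89 and 772 over 35, and 56 and 172 over 10. The values cannot be ranked at such unlike read numbers, and duplicate reads can also exceed counting noise. A change of roots with stage was not tested and stays open, with 1 library.

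Abundant seed loci had low values in both leaf libraries. Of 65 loci chosen without the leaf libraries, 64 were above 0 in leaves before flowering, at a median of 0.0883% of the seed level, and 63 in leaves after flowering, at 0.0667%. Reads carried over from the seed libraries are a candidate explanation, since the slope of log2 leaf value on log2 seed value was 0.91 (SE 0.0989), and leaf expression unrelated to the seed level is argued against by that slope together with the 98.5% of loci above 0. In the deeper library labelled roots sampled after flowering, 13 of 52 abundant seed loci were above 0. Those 52 were chosen to stand above the leaf libraries too, so they are not the same kind of set as the 65. Leaf expression in proportion to the seed level was not tested, and an earlier set of the 100 highest seed-specific loci of each seed library gave 96% to 99% above 0 in the leaf libraries.

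Of 106 loci abundant in mature seeds, 7 were listed at 0 in milk grains, although mature seeds held 1363 to 38067 FPKM there and the lowest of the other 99 values was 0.590. Failed abundance estimates and absence of these transcripts from milk grains cannot be told apart: the leaf level at the 7 loci had a median of 0.273% of mature seeds, above the median of 0.0621% but below the highest value of 0.696% at 35 loci with low milk grain values, and the criterion set first needed it to exceed that highest value. After that outcome was known, 10000 draws of as many of the 35 loci were added, and 0 reached 0.273%, with the highest draw at 0.270%. The draws were chosen because the first criterion decided nothing, so they are a description only, and both readings assume that the leaf values came from seed libraries.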

How the results depend on the processing

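The alternatives for loci under 300 bp, exact zeros, the doubted library and all organ-set medians were chosen after seeing the data. Of 168 alternative values, 125 stayed within 1.5 times the reported value (for organ-set medians, or within 0.1, and for the leaf and root correlation, within 0.1), 41 moved further and 2 reversed. A filter at 5 FPKM, median-ratio rescaling, leaving out zeros, keeping loci under 300 bp in the organ sets and detection limits of 0.1 and 5 FPKM moved none. Dropping the filter is not counted among these. It cannot change the counts of changed loci, since a locus under 1 FPKM in both libraries cannot pass the 4-fold limit, so it says nothing about stability. Median-ratio rescaling divided libraries by only 0.887 to 1.06, so it is a weak check. Other settings for the gene-list medians were not run, because no list could be matched. No paired analysis was possible because the compared groups share only replicate number 1. A contrast of the periods over leaves and roots, with organ as a block, was not run, since the label of 1 of its 4 libraries is in doubt. A 2-fold limit admits more loci by construction. It gave 3153 higher and 4081 lower for flowers, 4475 and 4324 for leaves, 9706 and 9762 for roots, and 8500 and 11149 for seeds, with 1544 loci enriched in inflorescences, 27 in flag leaves, 49 in roots and 1166 in seeds. A pseudocount of 0.1 gave 1923 and 2295 for flowers, 2500 and 2090 for leaves, 6858 higher for roots and 8564 lower for seeds, with 1163 enriched in inflorescences, 20 in roots and 807 in seeds. Rescaling to equal sums divided libraries by 2.13 to 5.31 with the pseudocount, and for counts the filter, still at 1. Its shifts therefore mix both effects, and within the leaf and root pairs the sums were already close. This rescaling gave 774 and 621 for leaves, 2807 and 3364 for roots and 1273 higher for seeds, with 286 enriched in seeds. It gave organ-set medians of -0.33 for inflorescence loci and 0.24 for root loci in leaves, -0.63 for inflorescence and -0.65 for seed loci in roots, and -0.46 for root loci in seeds. Without loci under 300 bp, 3 loci were enriched in flag leaves and 1 in roots, and without the library labelled roots sampled after flowering 492 and 2336. A 16-fold set limit gave medians of 1.34 for leaf loci in flowers, 0.71 for root loci in leaves, -0.81 for inflorescence and 5.48 for leaf loci in roots, and -0.058 for root loci in seeds. It reversed the median of inflorescence loci in leaves, to 0.61, and in seeds, to 1.01. The pseudocount of 0.1 shrinks ratios less, so like the 2-fold limit it can only admit more loci. The cause of the other shifts was not tested. Relative depth limits what a value of 0 shows, but the loci listed at 0 did not follow depth in order: 9183 in mature seeds (depth 1), 6959 in roots before flowering (1.65), 7561 in leaves before flowering (2.04), 4961 in flowers (2.41) and 5287 in the deepest library (7.79).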

Other observations

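All results in this part were chosen after seeing the data. Loci specific to inflorescences had low values in mature seeds. Whether the low values in this part are expression or reads carried over from another library was not tested. All 23 such loci, chosen without the seed libraries, were above 0 in mature seeds, at a median of 1.04% of the inflorescence level, against 0.0317% in milk grains, where 20 were above 0. The slope of log2 mature seed value on log2 inflorescence value was 1.26 (SE 0.232), and that of log2 milk grain value was 0.31 (SE 0.556). Loci specific to roots before flowering had low values in every other library. In mature seeds 34 of 42 were above 0, at a median of 0.182% of the root level and a slope of 1.23 (SE 0.234). In milk grains 26 of 42 were above 0, at 0.0247% and a slope of 0.63 (SE 0.503). In leaves before flowering 61 of 69 were above 0, at 0.321% and a slope of 1.31 (SE 0.335), and in leaves after flowering 57 of 69, at 0.419% and a slope of 0.17 (SE 0.465). Flower buds had 34 of 39 above 0, at 0.0340% and a slope of 0.53 (SE 0.396), and flowers 32 of 39, at 0.0519% and a slope of 1.00 (SE 0.399). The library labelled roots sampled after flowering had 33 of 34 above 0, at 0.0372% and a slope of 0.71 (SE 0.312). Its 34 loci were also chosen to stand above both leaf libraries, while the 69 loci for leaves were not, so its level is not comparable with theirs.

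Overlapping loci on opposite strands were compared for 3596 pairs that overlapped by at least 50% of the shorter locus. With loci of all lengths and zeros kept, as first run, pairs with both members at least 4-fold apart in the same direction numbered 44 of 45 in leaves, 208 of 263 in the libraries labelled roots, 130 of 189 in seeds and 6 of 12 in flowers. Pairing the same loci at random gave at most 29, 147, 116 and 12. With loci of at least 300 bp above 0 in both libraries, a restriction added afterwards, the counts were 16 of 17, 60 of 93, 54 of 96 and 1 of 4, and random pairing gave at most 15, 66, 63 and 5. Under the restriction only leaves lay above the random range, by 1 pair.

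Loci of at least 300 bp listed at 0 in a library although the median of the other libraries was at least 100 FPKM numbered 12 in mature seeds and between 1 and 3 in each other library.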
